A study of Rattus norvegicus with 47 samples.

How the data were processed

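Total RNA from rat tracheal explants was extracted with Trizol, amplified and biotin-labelled with the NuGEN system and hybridised to Affymetrix Rat230_2 arrays, per the labels' protocols. Each of 12 rats gave 4 explants, and the labels name 47 arrays in 8 groups: air, cigarette smoke, dexamethasone and both, at 2 h and at 24 h. Per the series text 1 further sample failed quality control; it is not among the arrays analysed here.

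The deposited table gives 1 intensity per probeset and array for 31099 probesets. The authors had put the arrays on a common scale by a method the labels do not state. The 75th percentile of an array lay between 617 and 640 at 2 h and between 600 and 613 at 24 h, and 49 to 96 probesets of an array were below 0, so a background had been subtracted. The intensities are linear, while the design had assumed log2 values; as laid down for that case, they were floored at 16 and put on the log2 scale. The 57 control probesets were left out of the tests, which leaves 31042. Arrays give no read depth, so no counting interval applies and their number limits the precision.

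Groups, contrasts, the test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. All 47 arrays were fitted in 1 linear model with a mean per group in limma 3.58.1 (R 4.3.3), with eBayes at its defaults. Each contrast was tested two-sided with Benjamini-Hochberg adjustment over the 31042 probesets and a threshold of 0.05. The contrasts were smoke against air, dexamethasone against air, and both treatments against each single treatment and against air, at each time, together with the interaction of smoke and dexamethasone, the change of each effect between the times, and air at 24 h against 2 h. Correlations of effects across probesets are descriptive.

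Probesets were assigned to genes from the platform table: 20826 had 1 gene symbol, 436 had several and 9780 had none. Of the former, 20758 were matched by gene ID to the RefSeq table of the GRCr8 assembly, which holds no coordinates here, so no positions are given. The probeset with the highest mean represents each of 14217 genes. Named genes are the 10 largest rises and falls that passed for smoke and for dexamethasone against air and the 5 largest otherwise, up to 4 members of each list that passed, and 18 genes named in advance; placeholder symbols were skipped. Of 34 gene lists with 638 entries, 568 entries were measured. Lists were tested with camera at its preset correlation of 0.01, beside camera with an estimated correlation and fry; list members were counted over all probesets and adjusted over the list alone.

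The fit was tested on simulated data made from the arrays with known changes added. At a log2 change of 1 it recovered 85% of the changed probesets for smoke at 2 h, 80% for smoke at 24 h, 86.2% for dexamethasone at 24 h and 68.8% for the interaction, and 2.5% to 9% of its calls were false. At a log2 change of 0.5 it recovered 55%, 52.5%, 56.2% and 31.2% in the same order. The simulated noise was independent between probesets and between arrays, with no effect of the rat. Changes were added only to brighter probesets. These shares therefore need not hold for the real arrays.

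Arrays with the same number at a time come from the same rat per the labels, so a fit with the rat as a block was run as an alternative. The deviations from the group means of same-number arrays correlated with a median r of 0.289 at 2 h and 0.163 at 24 h, against -0.0761 and -0.0487 for other pairs. Further alternatives were quantile normalization, median centring, a filter that removes probesets with a mean up to the 40th percentile, eBayes with trend and robust, array weights, only the groups compared in the fit, probesets averaged per gene, the number in the description label and the difference of 3' and 5' control probesets as covariates, and leaving out each array in turn. Added after the data were seen were a floor of 32, a block in which dexamethasone array 2 at 24 h is a rat of its own, a fit without the 3 arrays numbered 2 at 24 h, the dexamethasone effect pooled over both smoke conditions, the smoke score and the zinc-finger class. The smoke score projects an array's values on the mean difference between exposed and unexposed arrays of its time. Single values were compared by exact permutation tests.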

Results

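Gene expression was measured in tracheal explants, pieces of rat windpipe kept in culture, from 12 Sprague-Dawley rats, on Affymetrix Rat230_2 arrays. Per the labels, every rat gave 4 explants: 1 was kept in air, 1 received 10 puffs of cigarette smoke, 1 received dexamethasone (a synthetic glucocorticoid that suppresses inflammation), and 1 received both. RNA of 6 rats was taken at 2 h and that of 6 other rats at 24 h. The series holds 47 arrays: 6 in each of 7 groups and 5 in the smoke group at 24 h, where number 2 is absent. The median intensity of an array lay between 146 and 160, and 11.4% to 12.3% of its probesets lay below an intensity of 16. The number of arrays limits the precision. Below, an effect is a log2 fold change ± its standard error (SE) from limma, with n = 6 arrays per group except n = 5 for smoke at 24 h, and adjusted p-values cover the 31042 probesets tested in a comparison.

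The first comparison asks what smoke did within 2 h of exposure. The largest fall of a named gene against air was in Csf3, a granulocyte growth factor, by 2.60 on the log2 scale (SE 0.53, adjusted p = 0.00132). Sprr2d (-2.49 ± 0.42) and Lrtm2 (-2.24 ± 0.38) followed, and Trib3 and Chac1, both targets of the integrated stress response, changed by -2.18 ± 0.39 and -2.03 ± 0.37 (adjusted p = 0.000292 and 0.000402). Fosl1, a subunit of the transcription factor AP-1, fell to a level 3.69-fold lower (-1.88 ± 0.29, adjusted p = 5.5e-05), in 6 of 6 rats. Other falls were in Muc3 (-1.88 ± 0.34), Il24 (-1.82 ± 0.33) and Prss22 (-1.80 ± 0.30). Rises were smaller, and most of the largest were in zinc-finger genes, which encode DNA-binding proteins: Zfp799 rose 2.14-fold (1.10 ± 0.20, adjusted p = 0.000404), Zfp157 by 1.08 ± 0.22, Zfp41 by 1.00 ± 0.15, Rbak by 0.93 ± 0.14 and Zfp287 by 0.84 ± 0.12. In all, 1726 probesets passed (limma), 693 higher and 1033 lower with smoke, and 137 of them changed over 2-fold, 20 up and 117 down. Of the 58 named genes that passed, 54 moved the same way in all 6 rats. Here and below such genes were chosen because they passed on these same arrays, so these counts are not independent support.

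Of the 20 measured genes of the integrated stress response, 5 fell and none rose (11 fell when adjusted over the list alone). Of 30 inflammatory genes, 6 fell (9 adjusted over the list alone), among them the chemokine Ccl7 (-1.49 ± 0.28), the endothelial adhesion molecule Sele (-1.25 ± 0.28) and Il6 (-0.93 ± 0.19, adjusted p = 0.00136). Of 21 matrix proteases and inhibitors, 4 fell (6 adjusted over the list alone): Adamts4 (-0.93 ± 0.14), Plau (-0.89 ± 0.19), Adamts1 (-0.79 ± 0.12) and the inhibitor Timp1 (-0.76 ± 0.11). Of 29 glucocorticoid receptor targets, 7 fell (9 adjusted over the list alone), including Angptl4 (-1.26 ± 0.25) and Fam107a (-1.23 ± 0.27). Of 22 interferon-stimulated genes, 3 fell (4 adjusted over the list alone): Ifit3 (-1.57 ± 0.22), Cxcl10 (-1.28 ± 0.31) and Ifih1 (-0.95 ± 0.24). These 5 lists shifted down by camera with its preset correlation, but with an estimated correlation the adjusted p was 0.464 for the integrated stress response, the proteases and the receptor targets and 0.898 for the inflammatory and interferon genes. The falls in Krt6c (-1.72 ± 0.41) and Ngfr (-1.02 ± 0.18), both of basal cells, were among 3 in 19 basal and squamous markers (4 adjusted over the list alone), and Pfkfb3 (-0.77 ± 0.15) was 1 of 2 falls among 21 hypoxia and glycolysis genes (4 alone).

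Few targets of the pathways that sense and detoxify smoke passed at 2 h. Of 9 targets of the aryl hydrocarbon receptor, which senses compounds in smoke, 2 rose (3 adjusted over the list alone): Tiparp (0.49 ± 0.12, adjusted p = 0.0104) and Nqo1 (0.35 ± 0.10, adjusted p = 0.0325). Without air array 2 the value for Nqo1 was 0.29 and its adjusted p was 0.117. The receptor's best known target, Cyp1a1, lay below an intensity of 16 on all 6 air and all 6 smoke arrays, so no fold can be given. Of 26 antioxidant targets of NRF2, 1 rose and 4 fell (the same numbers adjusted over the list alone), with a median of 0.03 and a mean of -0.09, which differ in sign. The cystine transporter Slc7a11 was the largest fall (-1.34 ± 0.24, adjusted p = 0.000402), while Hmox1 (-0.49 ± 0.19, adjusted p = 0.126) and Gclm (-0.01) did not pass. Of 21 immediate early genes, Junb (0.72 ± 0.11) and Ier2 (0.67 ± 0.08) rose and Fosl1 fell, and of 17 heat shock genes Hsph1 rose (0.34 ± 0.07) and 1 fell. No member of the cell cycle (29 genes), ciliated (18) or secretory (20) lists passed.

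At 24 h smoke changed more probesets than at 2 h, and cell division genes led the falls. Top2a, the DNA topoisomerase of dividing cells, was 11.5-fold lower with smoke than in air (-3.53 ± 0.40, adjusted p = 4.52e-08), in 5 of 5 rats. The other large falls were mostly in genes of DNA replication and mitosis: Cdca3 (-3.32 ± 0.42), E2f8 (-3.13 ± 0.43), Pclaf (-3.11 ± 0.37), Shcbp1 (-2.96 ± 0.43) and the kinases Pbk (-2.87 ± 0.35) and Ttk (-2.74 ± 0.34). Apod, which encodes a lipid-binding apolipoprotein, fell as far (-3.35 ± 0.42). Large rises were in Ryr1, the calcium release channel of skeletal muscle (2.90 ± 0.47, adjusted p = 1.48e-05), in Tac1, the precursor of substance P (2.86 ± 0.52), in Trim72, a membrane repair protein of muscle (2.77 ± 0.33), in Mest (2.63 ± 0.22) and in the inflammasome sensor Nlrp6 (2.62 ± 0.28). Btnl5, which passed as well, lay at the floor on all 6 air and on 2 of the 5 smoke arrays and was higher in 3 of 5 rats, so no fold is given. In all, 7276 probesets passed, 3745 higher and 3531 lower (4525 and 2951 with median centring, 3158 and 3232 with the filter on dim probesets), with 946 changed over 2-fold (361 up, 585 down). With only these groups in the fit 4704 passed. Of the 126 named genes that passed, 99 moved the same way in all 5 rats with both arrays.

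Of 29 cell cycle genes 23 were lower with smoke at 24 h and none was higher (25 lower adjusted over the list alone; adjusted p = 0.155 with an estimated correlation). The list's median was -1.14. Cdk1, the kinase that drives mitosis, changed by -2.57 ± 0.37, the replication helicase subunit Mcm5 by -2.12 ± 0.32 and cyclin A, Ccna2, by -2.04 ± 0.31. Heat shock genes rose, 15 of 17 (all 17 adjusted over the list alone), led by Hspa1a, the inducible HSP70 (3.44-fold, 1.78 ± 0.24), Hspb8 (1.07 ± 0.13), Cryab (1.01 ± 0.26) and Dnajb1 (0.99 ± 0.13). This was the 1 list of 34 whose shift passed with an estimated correlation (adjusted p = 0.0453). Immediate early genes rose in 14 of 21 cases (17 alone; adjusted p = 0.233 with an estimated correlation), including Fosl1 (1.73 ± 0.31), Arc (1.32 ± 0.27) and Nr4a2 (1.11 ± 0.19). p53 targets rose in 7 of 16 cases and fell in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.0581 with an estimated correlation), including Plk2 (0.95 ± 0.17), Phlda3 (0.91 ± 0.19), the nuclease Aen (0.79 ± 0.13) and Cdkn1a, the cyclin kinase inhibitor p21 (0.63 ± 0.13).

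Of the 9 aryl hydrocarbon receptor targets, 5 rose at 24 h (5 adjusted over the list alone; adjusted p = 0.157 with an estimated correlation): Cyp1a1 rose 3.92-fold (1.97 ± 0.31, adjusted p = 8.24e-06, in 5 of 5 rats), and Cyp1a2, at the floor on all 6 air arrays, was higher by at least 1.29 (SE 0.19). Of 26 NRF2 targets, 12 rose (14 adjusted over the list alone; adjusted p = 0.301 with an estimated correlation), among them Gclm, a subunit of the enzyme that starts glutathione synthesis (0.73 ± 0.11, adjusted p = 8.05e-06), Akr7a3 (1.18 ± 0.25), Osgin1 (0.82 ± 0.20) and Nqo1 (0.46 ± 0.11); Hmox1 did not pass (0.30, adjusted p = 0.302). Of 20 integrated stress response genes, 10 rose (11 alone; adjusted p = 0.823 with an estimated correlation), with Ppp1r15a (1.22 ± 0.22), Sesn2 (1.16 ± 0.27) and Atf3 (0.98 ± 0.23) among them. Of 18 chaperones and related genes of the endoplasmic reticulum 4 were lower and 1 was higher (6 and 1 alone; adjusted p = 0.933 with an estimated correlation). Of the 4 lower ones Pdia6 (-0.47 ± 0.09) passed with any single array left out. Sdf2l1, Pdia4 and Xbp1 did not pass without smoke array 6 (-0.36, -0.35 and -0.27; adjusted p = 0.171, 0.102 and 0.126). Nor did Sdf2l1 pass without air array 3 or 6 or smoke array 4 or 5. The same held for Pdia4 without air array 3 or smoke array 5, and for Xbp1 without air array 1, 3, 4, 5 or 6 or smoke array 1, 4 or 5. With smoke at 24 h 1859 of all 14217 genes were higher, and 3531 of the 31042 probesets were lower, so some members of any list can pass. Whether the inflammatory, growth factor, protease and interferon counts that follow exceed these shares was not tested. None of these lists shifted with an estimated correlation. Of 30 inflammatory genes 5 rose and 3 fell (6 and 3 adjusted over the list alone). The neutrophil chemokine Cxcl2 (1.03 ± 0.28) and Il6 (0.65 ± 0.20) were up, and Ccl20 (-2.52 ± 0.41) and Lcn2 (-1.12 ± 0.20) were down. Growth factors of the EGF receptor rose (Areg 1.37 ± 0.37, Hbegf 0.88 ± 0.25) while Egf fell (-0.71 ± 0.21), within a list where 2 rose and 4 fell of 10 (the same numbers alone). Among 21 proteases and inhibitors 3 rose and 3 fell (the same numbers alone), with Mmp10 (1.69 ± 0.27) up and Mmp7 (-1.73 ± 0.36) and Adamts5 (-1.19 ± 0.29) down. Of 22 interferon-stimulated genes 3 rose and 1 fell (the same numbers alone), Cxcl10 (1.81 ± 0.33) and Oasl (1.16 ± 0.26) among the rises.

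Markers of several airway cell types were lower with smoke at 24 h. Of 20 secretory and goblet cell markers, 11 fell and none rose (11 adjusted over the list alone; adjusted p = 0.0581 with an estimated correlation): Agr2, which folds mucins (-1.87 ± 0.25, adjusted p = 8.29e-07), the goblet cell regulator Spdef (-1.72 ± 0.30), Lypd2 (-1.31 ± 0.22) and Clca1 (-1.17 ± 0.19). Scgb1a1, the secretoglobin of club cells, fell by less (-0.29 ± 0.08, adjusted p = 0.00648). Of 18 ciliated cell markers, 11 fell (14 adjusted over the list alone; adjusted p = 0.815 with an estimated correlation), among them Tekt2 (-1.32 ± 0.33), Dnai1 (-1.03 ± 0.30) and Dynlrb2 (-0.93 ± 0.20), whereas Foxj1 did not pass (-0.52, adjusted p = 0.116; with the rat as a block -0.51 and 0.0267). Mast cell markers fell in 4 of 10 cases (alone 4 fell and 2 rose), including Fcer1a (-1.74 ± 0.41) and Hdc (-1.02 ± 0.20). Schwann cell markers fell in 3 of 11 cases (alone 3 fell and 1 rose), including Gfap (-1.95 ± 0.45) and Scn7a (-1.31 ± 0.24). Endothelial markers fell in 4 of 13 (4 alone), Vwf among them (-0.94 ± 0.28), and of 20 macrophage markers 3 fell but 0 did so when adjusted over the list alone. The macrophage markers C1qb and C1qc moved in the direction of their call in only 2 of 5 rats each. Red blood cell genes were higher in 4 of 6 cases (4 alone; adjusted p = 0.301 with an estimated correlation), Hbb by 0.99 ± 0.26. Basal and squamous markers went both ways (3 rose and 3 fell of 19, and the same alone), with Sprr1a (1.66 ± 0.44) up and Ngfr (-0.81 ± 0.19) down. Among 14 fibroblast markers, Dpt rose (0.79 ± 0.14) and 3 fell (the same alone), Lum by -0.73 ± 0.17. The counts of these marker lists were likewise not tested against the shares of all genes and probesets.

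**Figure D1:**
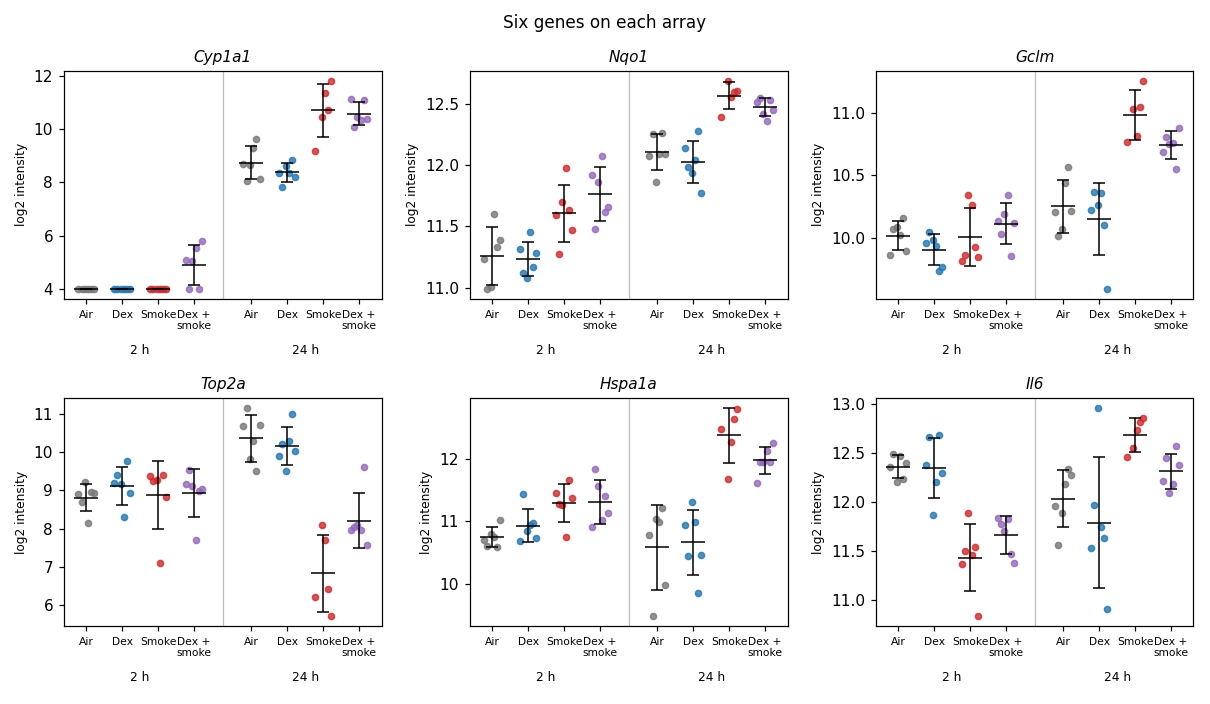
Log2 intensity (y axis) of 6 genes on each array by group (x axis); points are arrays, ordered by rat number within a group, and bars are the group mean ± SD. Top2a is lower and Cyp1a1, Gclm and Hspa1a are higher in both smoke groups than in both unexposed groups at 24 h, and Cyp1a1 lies at the floor on all 6 air arrays at 2 h.

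The same question was asked in the presence of dexamethasone, by setting both treatments against dexamethasone alone. At 2 h Zfp799 again rose (1.07 ± 0.20, adjusted p = 0.00372), as did Zfp111 (0.85 ± 0.14), Rbak (0.85 ± 0.14) and Nqo1 (0.53 ± 0.10, adjusted p = 0.00456, in 6 of 6 rats). The largest fall was in Sprr2d (-1.80 ± 0.42), which did not pass without array 1, 5 or 6 of both treatments or dexamethasone array 2 or 4 (adjusted p 0.0558, 0.0565, 0.087, 0.0579 and 0.0568). Large falls that passed with any single array left out were in the cytokine Il24 (-1.69 ± 0.33), Tnfaip6 (-1.55 ± 0.30) and the chemokine Cxcl9 (-1.49 ± 0.29). Of 30 inflammatory genes 3 fell (9 adjusted over the list alone; adjusted p = 0.526 with an estimated correlation), with Sele (-1.42 ± 0.28) and Ccl7 (-1.41 ± 0.28) among them. Of 21 proteases and inhibitors 3 fell (4 alone; adjusted p = 0.526 with an estimated correlation), Adamts4 (-0.77 ± 0.14) and Timp1 (-0.55 ± 0.11) included, and of 22 interferon-stimulated genes 3 fell (6 alone; adjusted p = 0.422 with an estimated correlation), Ifit3 by -1.25 ± 0.22. Aryl hydrocarbon receptor targets rose in 2 of 9 cases (4 alone, adjusted p = 0.0835 with an estimated correlation), while of the 20 integrated stress response genes 0 passed (1 fell when adjusted over the list alone). Cyp1a1 did not pass over all probesets. It lay at the floor on all 6 dexamethasone arrays but on only 2 of the 6 with both treatments. Their mean log2 intensity was 4.90, near the floor of 4, so no fold is given. In all 404 probesets passed, 184 higher and 220 lower, 716 with the rat as a block and 13 with only these groups in the fit. Within rats, 23 of the 25 named genes that passed moved the same way in all 6 rats. The count was 666 without dexamethasone array 3, between 200 and 252 without dexamethasone arrays 1 (250), 2 (204), 4 (252) or 5 (200), and 231 or 142 without array 5 or 6 of both treatments.

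With dexamethasone at 24 h, smoke again raised Tmem200c (2.29 ± 0.21, adjusted p = 3.06e-09), Cyp1a1 (4.64-fold, 2.22 ± 0.29, adjusted p = 7.39e-06, in 5 of 5 rats), Ryr1 (1.88 ± 0.45) and Mest (1.79 ± 0.21). It lowered Cdca3 (-2.40 ± 0.41), Apod (-2.32 ± 0.40), Pbk (-2.21 ± 0.33), Dpp6 (-1.98 ± 0.30) and Sftpa1, a surfactant protein (-2.21 ± 0.40). Cell cycle genes fell in 16 of 29 cases (alone 21 fell and 1 rose; adjusted p = 0.173 with an estimated correlation), Top2a by -1.95 ± 0.38. Heat shock genes rose in 10 of 17 cases (11 alone; adjusted p = 0.0954 with an estimated correlation), Hspa1a by 1.30 ± 0.23. The p53 targets rose in 6 of 16 cases (7 alone), Phlda3 by 0.84 ± 0.19, and this was the 1 list that passed with an estimated correlation (adjusted p = 0.0278). NRF2 targets rose in 7 of 26 cases (10 alone; adjusted p = 0.187 with an estimated correlation), Gclm by 0.59 ± 0.11. Secretory markers fell in 6 of 20 cases (8 alone; adjusted p = 0.111 with an estimated correlation), Agr2 by -1.49 ± 0.24. The goblet cell mucin Muc5ac lay at the floor on 5 of the 6 arrays with both treatments and 2 of the 6 with dexamethasone. It was lower (fitted value -1.30 ± 0.41, adjusted p = 0.0454) in 3 of 5 rats, but with these floors that value is not a measured size. Without dexamethasone array 1 the fitted value was -1.01 and its adjusted p was 0.145. Chaperones of the endoplasmic reticulum fell in 6 of 18 cases (14 alone; adjusted p = 0.192 with an estimated correlation), Pdia6 by -0.43 ± 0.08. No ciliated marker passed. In all 2281 probesets passed, 1013 higher and 1268 lower, (1343 and 1038 with median centring, 688 and 546 with only these groups in the fit). With the rat as a block the count was 2711 when dexamethasone array 2, which does not match its number, was a rat of its own, and 3447 otherwise. It was 4140 with array weights and 1226 without the arrays numbered 2. Within rats, 56 of the 74 named genes that passed moved the same way in all 5 rats whose arrays match.

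The smoke effects without and with dexamethasone, which share no array, were alike at both times. At 2 h their log2 fold changes correlated across the 31042 probesets with r = 0.592, and at 24 h with r = 0.739. Probesets are not independent replicates. The jackknife SE, with each of the 12 rats left out in turn, was 0.130 and 0.0899. Only the 6 rats of a time can change its r, so these values are not the SE over those 6 rats. Without any 1 rat r lay between 0.485 and 0.610 at 2 h and between 0.651 and 0.745 at 24 h. At 2 h 133 probesets were higher in both comparisons, against 4.11 if calls were independent, 191 were lower in both, against 7.32, and 0 were opposite. At 24 h 844 were higher in both, against 122, 991 were lower in both, against 144, and 1 was opposite.

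**Figure D2:**
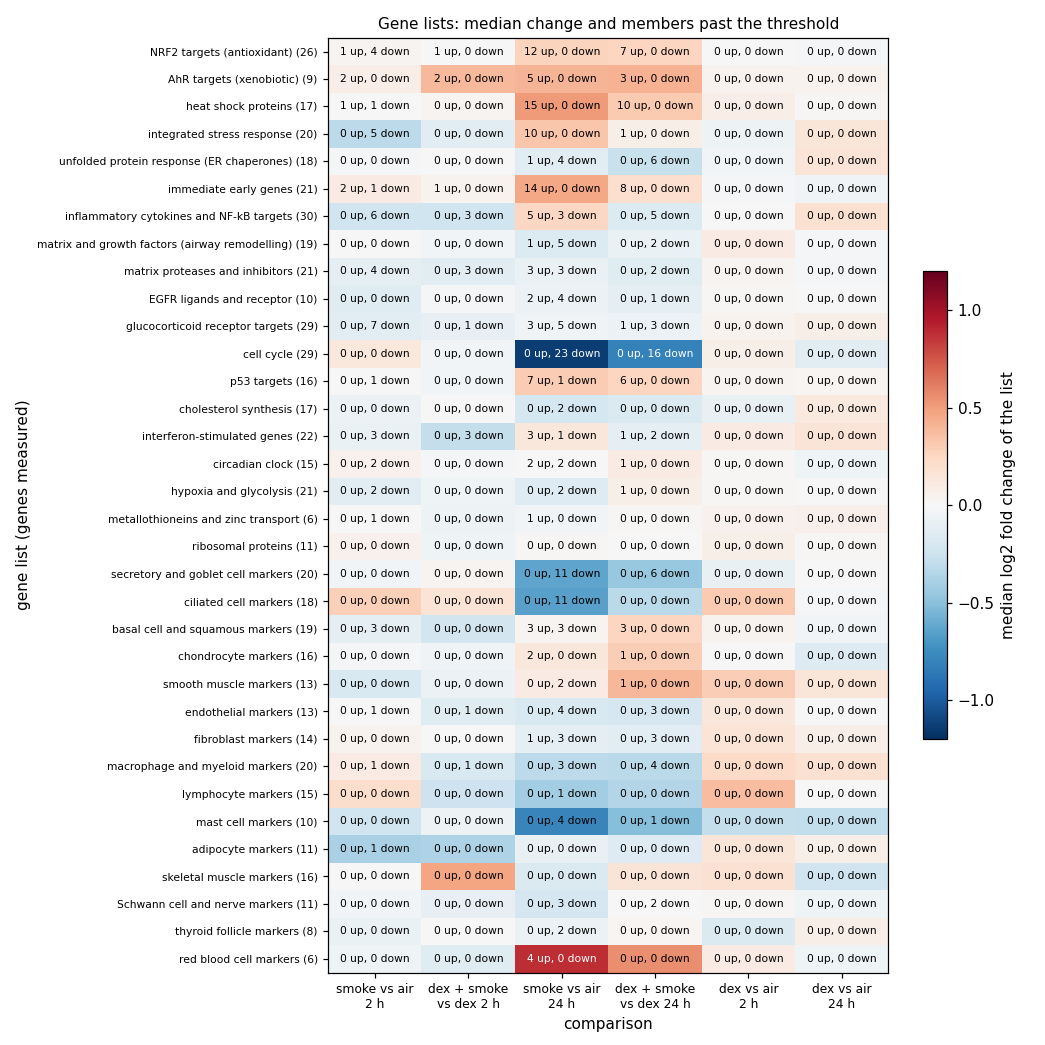
Gene lists (y axis, with the number of genes measured) in 6 comparisons (x axis); the colour is the median log2 fold change of a list and each cell gives how many members rose and fell past an adjusted p of 0.05. Cell cycle genes fall with smoke at 24 h without (23 of 29) and with dexamethasone (16), and heat shock genes rise (15 and 10 of 17). With an estimated correlation the adjusted p is 0.155 and 0.173 for the cell cycle and 0.0453 and 0.0954 for heat shock.

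Dexamethasone alone was set against air to ask what the steroid did without smoke. At 2 h 0 probesets passed (limma; 1637 had an unadjusted p under 0.05), and at 24 h 1 passed (1191 unadjusted). That probeset belongs to Ace, the angiotensin-converting enzyme, and rose by 1.17 ± 0.20 (adjusted p = 0.0314). It is named after its value was seen. A brighter probeset of Ace did not pass. The called probeset had a mean log2 intensity of 6.16, and with the filter on dim probesets the count was 0. Fkbp5, a classical target of the glucocorticoid receptor, was 0.37 ± 0.18 at 2 h (adjusted p = 0.941) and 0.42 ± 0.18 at 24 h (adjusted p = 1). Tsc22d3, which encodes GILZ, was 0.16 ± 0.12 and 0.25 ± 0.12, Per1 was 0.12 ± 0.13 and 0.05 ± 0.13, and the cytokine Il6 was -0.01 ± 0.19 and -0.24 ± 0.19; none of these passed. None of the 29 receptor targets passed at either time, over all probesets or adjusted over the list alone, and their medians were 0.04 and 0.07. By camera 15 lists at 2 h and 10 at 24 h shifted with the preset correlation, and 0 did at either time with an estimated correlation (lowest adjusted p 0.679 and 0.711). The Ace call was absent (a count of 0) without air array 3, 5 or 6 or dexamethasone array 1 or 6. The 24 h count was 3 with the rat as a block (1 with dexamethasone array 2 as a rat of its own), 9 with array weights, 0 with only these groups in the fit, and 9, 2 and 4 without air array 1, 2 or 4, and 4, 3 and 6 without dexamethasone array 3, 4 or 5. The 2 h count was 2 with array weights and 1 without air array 2, 3, 5 or 6.

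Because each rat gave all 4 explants, the effect of dexamethasone was also taken over both smoke conditions within rats, with the rat as a block and dexamethasone array 2 at 24 h as a rat of its own; this was chosen after the single comparison was seen. At 2 h 12 probesets passed, 11 of them higher, and at 24 h 29, 20 higher and 9 lower (5 and 9 without the block). At 2 h Fkbp5 rose by 0.46 ± 0.09 (adjusted p = 0.0461) and on its other probeset by 0.75 ± 0.12 (adjusted p = 0.0066). Tchh, which encodes the hair follicle protein trichohyalin, rose by 1.65 ± 0.24 (adjusted p = 0.00213), Ctps1, an enzyme of CTP synthesis, by 0.33 ± 0.05, Map3k6 by 0.51 ± 0.09 and Ccn2, a matrix growth factor, by 0.18 ± 0.04 (adjusted p = 0.0494), while Fat3 fell by 0.49 on the log2 scale. At 24 h Ace rose by 0.99 ± 0.14 (adjusted p = 0.00234) on the probeset named above, while its brighter probeset did not pass. Igfbp3 rose by 0.61, Crispld2 by 0.43 and Txnip by 0.33 (adjusted p = 0.0186, 0.0299 and 0.0086), and Fkbp5 did not pass (0.42, adjusted p = 0.0616). Without the block Tchh, Fat3, Ace and Txnip passed as well, but both probesets of Fkbp5 at 2 h (adjusted p = 0.467 and 0.238), Ctps1 (0.311), Map3k6 (0.085), Ccn2 (0.203), Igfbp3 (0.194) and Crispld2 (0.0825) did not. Over both times Fkbp5 was higher with dexamethasone in 20 of 22 same-rat pairs. The 2 pairs of a rat, with and without smoke, are not independent. Their mean was above 0 in 11 of 11 rats (exact binomial p = 0.000977, two-sided, the smallest that 11 rats allow).

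Both treatments were set against smoke alone to ask what dexamethasone did in smoke-exposed explants. At 2 h Tchh rose 5.59-fold (2.48 ± 0.37, adjusted p = 0.00122, in 6 of 6 rats). Its mean log2 intensity was 8.41 (SD 1.51) with smoke, 10.02 (0.31) in air, 10.84 (0.46) with dexamethasone and 10.90 (0.44) with both. The smoke group was thus low and variable, and the level with both was close to that with dexamethasone alone. The pooled effect of Tchh above averages a larger difference with smoke and a smaller one without it. The other 3 probesets that passed have no gene name in the platform table (1.26, 1.13 and 0.67, all higher) and are given after their values were seen. Of the 29 glucocorticoid receptor targets 0 passed over all probesets, while 7 rose when adjusted over the list alone (adjusted p = 0.0702 with an estimated correlation). The 2 h count of 4 (904 unadjusted) was 8 with the rat as a block, 12 with array weights, and 0, without Tchh, with only these groups in the fit. It was 2, 8 or 14 without array 4, 5 or 6 of both treatments, and 2, 10, 10 or 2 without smoke array 1, 3, 4 or 6.

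At 24 h dexamethasone lowered the monocyte chemokine Ccl2 in smoke-exposed explants (-0.90 ± 0.20, adjusted p = 0.0325), together with Tex19.2 (-1.39 ± 0.24) and the heat shock genes Hspb8 (-0.56 ± 0.13) and Stip1 (-0.29 ± 0.06). Cyp1a2, at the floor on 3 of the 6 arrays with both treatments and near it on average (4.21 in log2, floor 4), was lower than with smoke alone (5.29; adjusted p = 0.00942); the floor limits the size of this fall. Dexamethasone raised Cyp2t1 (1.10 ± 0.23) and Aqp4, a water channel (1.04 ± 0.20, adjusted p = 0.0175). Heat shock genes fell in 2 of 17 cases (8 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation). In all 112 probesets passed, 51 higher and 61 lower (35 and 101 with median centring, 42 and 24 with the filter on dim probesets, 58 and 55 with trend and robust). The count was 379 with array weights and 55 without the arrays numbered 2. Within rats, 9 of the 12 named genes moved the same way in all 5 rats. None of the 12 named genes passed without smoke array 6 (Ccl2 -0.83, adjusted p = 0.195; Cyp1a2, adjusted p = 0.0506), where the count was 7. The count was 1110 or 18 without smoke array 3 or 5, and 61, 56, 10, 28 or 171 without array 1, 2, 3, 4 or 5 of both treatments, and 0 with only these groups in the fit.

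The interaction asks whether the smoke effect differed with dexamethasone. At 2 h 0 probesets passed (limma; 816 unadjusted) and at 24 h 1 (2301 unadjusted), a probeset of the RNA-binding protein gene Rbm11 (adjusted p = 0.00283). Its intensities all lay under 32, and at 24 h it was at the floor on 5 of 6 air arrays, all 6 with dexamethasone and 2 of 6 with both treatments, so no size is given. Rbm11 did not pass with a floor of 32, with only these groups in the fit, with the rat as a block and dexamethasone array 2 as a rat of its own (adjusted p = 0.0504), or without the 3 arrays numbered 2 (adjusted p = 0.0527). No member of any list passed; adjusted over the list alone, 4 heat shock genes had a smaller smoke effect at 24 h (adjusted p = 0.406 with an estimated correlation). The 24 h count was 19 with array weights, 157 without smoke array 3, 2 without smoke array 4 or 5, 2 or 3 without array 2 or 5 of both treatments, and 5, 2, 2 or 2 without dexamethasone array 1, 4, 5 or 6.

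A score chosen after these results summarised the smoke response of each array, with 0 the mean of unexposed and 1 the mean of exposed arrays of a time. At 24 h it was 1.24 ± 0.276 (SD, n = 5) with smoke and 0.801 ± 0.133 (SD, n = 6) with both treatments, a difference of -0.438 (exact permutation p = 0.0108, two-sided, 462 splits), and it was lower with both in 5 of 5 rats (mean -0.450, exact sign-flip p = 0.0625, the smallest that 5 rats allow). Air and dexamethasone lay at 0.0233 ± 0.186 and -0.0233 ± 0.173 (SD, n = 6 each), and the interaction of the score was -0.392 (permutation p over arrays 0.0593). Within the 5 rats with all 4 arrays in place the interaction was negative in 5 of 5 (mean -0.377, SD 0.173, exact sign-flip p = 0.0625, the smallest that 5 rats allow). At 2 h the scores were 1.11 ± 0.169 and 0.895 ± 0.239 (SD, n = 6 each), a difference of -0.210 (exact permutation p = 0.108), with an interaction of -0.230 (permutation p = 0.215).

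**Figure D3:**
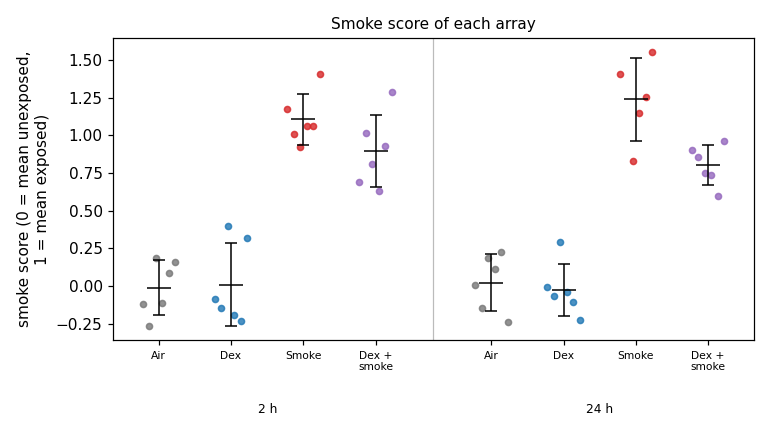
Smoke score of each array (y axis, no unit, 0 is the mean of unexposed and 1 that of exposed arrays of the time) by group (x axis); points are arrays, ordered by rat number, and bars are the group mean ± SD. At 24 h the smoke arrays average 1.24 and those with both treatments 0.801.

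Both treatments together were compared with air. At 2 h Sele (-1.54 ± 0.28, adjusted p = 0.00188), Trib3 (-1.73 ± 0.39), Ccl7 (-1.50 ± 0.28), Ccl2 (-0.88 ± 0.19) and Adamts4 (-0.86 ± 0.14) fell, and Zfp799 (0.94 ± 0.20), Tiparp (0.57 ± 0.12) and Nqo1 (0.51 ± 0.10, adjusted p = 0.00428, in 6 of 6 rats) rose. Aldh3a1, an aldehyde dehydrogenase, rose by 1.13 ± 0.29 (adjusted p = 0.029; without air array 2, 0.99 and 0.118). Aryl hydrocarbon receptor targets rose in 3 of 9 cases (5 alone), the 1 list that passed with an estimated correlation (adjusted p = 0.0233), and inflammatory genes fell in 4 of 30 (8 alone; adjusted p = 0.69 with an estimated correlation). The count was 515 (189 higher, 326 lower), 1012 with the rat as a block, 973 with array weights and 131 with only these groups in the fit. Within rats, 21 of the 29 named genes that passed moved the same way in all 6 rats. The count was 309 or 239 without air array 1 or 2, and 292, 323 or 317 without array 2, 5 or 6 of both treatments.

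At 24 h both treatments together raised Cyp1a1 (1.85 ± 0.29, adjusted p = 0.000147), Tmem200c (2.08 ± 0.21), Trim72 (1.79 ± 0.31) and Mest (1.77 ± 0.21), and lowered Top2a (-2.15 ± 0.38), Cdca3 (-2.59 ± 0.41) and the mast cell proteases Mcpt8 (-2.55 ± 0.62) and Mcpt1 (-2.18 ± 0.37). The p53 targets (5 of 16 higher, 8 alone), the aryl hydrocarbon receptor targets (4 of 9, 4 alone) and the heat shock genes (8 of 17, 11 alone) passed as lists with an estimated correlation (adjusted p = 0.00462, 0.036 and 0.036). Cell cycle genes fell in 17 of 29 cases (23 alone; adjusted p = 0.0531 with an estimated correlation). The count was 1813 (919 higher, 894 lower) and 2908 with the rat as a block (1411 higher, 1497 lower), and 3668 with array weights. Within rats, 37 of the 57 named genes that passed moved the same way in all 6 rats. The count was 1207 or 1111 without air array 2 or 6, 1130 or 1159 without array 2 or 6 of both treatments, and 681 without the 3 arrays numbered 2 at 24 h, of which the dexamethasone array does not match its rat.

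The change of the smoke effect from 2 h to 24 h was tested directly, between different rats. It was largest upward in Tac1 (3.76 ± 0.71), Fosl1 (3.61 ± 0.43, adjusted p = 2.58e-07), Xirp1 (3.47 ± 0.51), Csf3 (3.39 ± 0.76) and Lgals4 (3.29 ± 0.53), and downward in E2f8 (-3.69 ± 0.59), Top2a (-3.59 ± 0.55), Cdca3 (-3.42 ± 0.59), Hsd17b6 (-3.38 ± 0.95) and Pclaf (-3.16 ± 0.51). Integrated stress response genes shifted up in 13 of 20 cases (13 alone; adjusted p = 0.347 with an estimated correlation), with Chac1 (3.02 ± 0.54) and Trib3 (2.59 ± 0.56) among them, both lower with smoke at 2 h. Ciliated markers shifted down in 10 of 18 cases (17 alone; adjusted p = 0.61 with an estimated correlation), and cell cycle genes in 21 of 29 (22 alone; adjusted p = 0.305 with an estimated correlation). Gclm (0.74 ± 0.16) and Il6 (1.58 ± 0.27) shifted up. For Cyp1a1, at the floor on all 6 air and all 6 smoke arrays at 2 h, no change of the effect can be given. In all 5522 probesets passed, 2890 up and 2632 down (3305 and 2186 with median centring). Across probesets, which are not independent replicates, the smoke effects at both times had r = -0.0717 (jackknife SE 0.0842), and 293 probesets were called in opposite directions against 203 if calls were independent. For the dexamethasone effect 0 probesets passed (limma; 1000 unadjusted), or 1 without dexamethasone array 4 at 24 h.

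Air at 24 h was set against air at 2 h as background for the time comparisons; the rats differ. The largest rises were in the matrix proteases Mmp3 (63.8-fold, 5.99 ± 0.41, adjusted p = 1.12e-15) and Mmp7 (4.74 ± 0.35), in the acute phase gene Saa3 (5.68 ± 0.42), in Cda (5.34 ± 0.36) and in Cyp1a1, at the floor on all 6 arrays at 2 h and higher by at least 4.75 (SE 0.29). The largest falls were in Sele (-4.66 ± 0.28), Cxcl10 (-4.50 ± 0.31) and Cyp2a3 (-4.50 ± 0.42). Hypoxia and glycolysis genes rose in 20 of 21 cases (20 alone), Car9 by 3.92 ± 0.55, and cell cycle genes in 23 of 29, with 2 lower (the same alone), Mcm5 by 2.65 ± 0.31. Immediate early genes fell in 18 of 21 cases and rose in 1 (the same alone), Nr4a1 by -3.57 ± 0.23, and interferon-stimulated genes fell in 19 of 22 (19 alone). Markers of smooth muscle (10 of 13, 10 alone), cartilage (13 of 16, 14 alone), lymphocytes (12 of 15, 13 alone), fibroblasts (10 of 14, 10 alone) and mast cells (8 of 10, 8 alone) fell, Myl9 by -3.70 ± 0.39. No list passed with an estimated correlation (lowest adjusted p 0.402). Fkbp5 rose (0.89 ± 0.18) and Per1 fell (-1.56 ± 0.13). In all 15858 probesets passed, 8323 higher and 7535 lower. The difference between 3' and 5' control probesets, a measure of RNA quality, averaged beta-actin and GAPDH. Its value was smaller at 24 h (-0.19 on the log2 scale, exact permutation p = 0.00216, two-sided). The drop came from GAPDH (1.17 to 1.31 on air arrays at 2 h, 0.828 to 0.942 at 24 h). For beta-actin the ranges overlapped (2.86 to 3.08 and 2.79 to 3.10), so a change of RNA quality is not shown.

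The arrays of a rat were compared through 205 probesets that separate the rats at 2 h, with limits set after looking at the data. At 24 h 22 of 23 arrays correlated best with an array of their own number (median r of same-number pairs 0.754). Dexamethasone array 2 at 24 h did not: its highest r with an array of its number was -0.174. Xist, a transcript of the inactive X chromosome, had an intensity of 5642 on that array, against 14.8 on air array 2 and 147 on array 2 of both treatments, and the Y-linked Eif2s3y had 8.80, against 1312 and 1414.

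**Figure D4:**
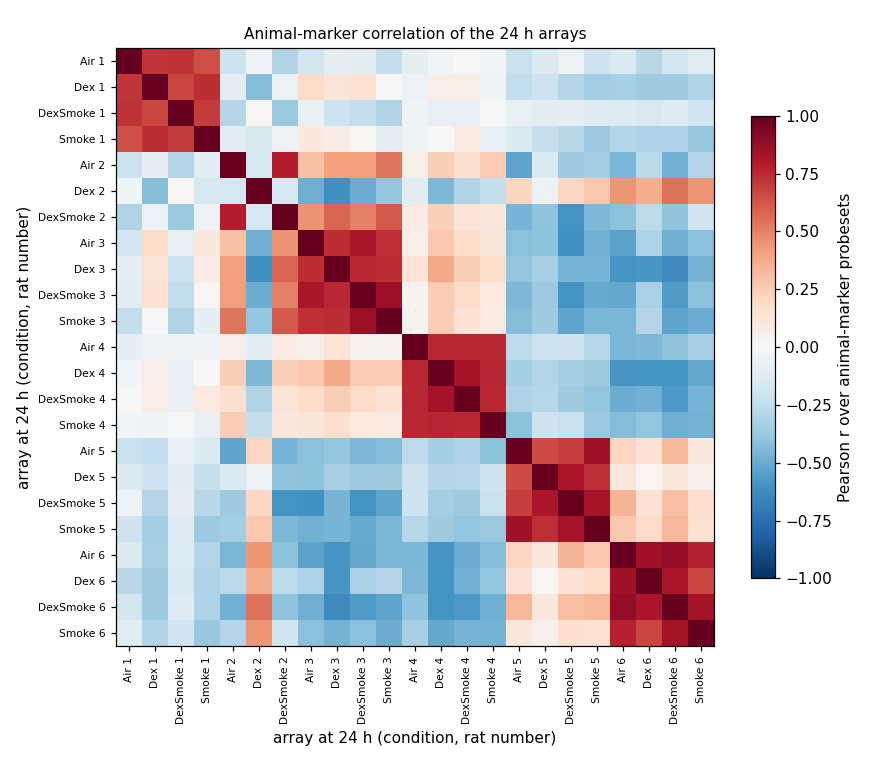
Pearson correlation (colour) between the 23 arrays at 24 h over 205 animal-marker probesets; both axes list the arrays by rat number and condition. Arrays of the same number correlate (median 0.754), except dexamethasone array 2.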

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

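Every test of an explanation in this part was chosen only after the result was seen, except the normalization and RNA quality tests of the smoke score; the splits of the pooled dexamethasone effect also came after.

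Dexamethasone array 2 at 24 h differs from the arrays of its number. A swap with another array at 24 h would leave a partner out of place, and 0 other arrays at 24 h matched another number best; the treatment is also argued against, since each of the other dexamethasone arrays at 24 h reached an r of at least 0.740 with its own number. An array from another animal remains a candidate explanation: the highest correlation with its number was -0.174, and its best match was array 6 of both treatments at 0.547. The rat of its number is argued against by the Y-linked Eif2s3y. It had 8.80 on this array, against 1312 on air array 2 and 1414 on array 2 of both treatments. Its highest r was 0.488 with a 24 h rat (rat 6) and 0.451 with a 2 h rat (rat 5). The lowest r of the other same-number pairs at 24 h was 0.643, so which animal the array came from stays open.

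Dexamethasone changed few probesets in the single comparisons. Labels exchanged throughout are argued against, because Fkbp5 was higher under dexamethasone in 20 of 22 same-rat pairs and on average in 11 of 11 rats. An effect too small for the single comparison is a candidate explanation, since the effect over both smoke conditions within rats gave 12 probesets at 2 h and 29 at 24 h. Steroid already in the culture cannot be told apart from a weak response, as no array without culture exists; the median receptor target changed by -0.15 (log2) in air from 2 h to 24 h.

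The smoke score at 24 h was smaller with dexamethasone than without. Scaling of the arrays as the whole cause is argued against by a difference of -0.437 after quantile normalization, though the deposited values were on a common scale already, RNA quality by -0.438 with the covariate, and a single array by -0.353, the value nearest 0 with 1 array left out (array 5 of both treatments; -0.546 without smoke array 3). A dampened smoke response under dexamethasone may explain it. Within rats the interaction of the score was negative in 5 of 5 (mean -0.377, SD 0.173), but 5 rats allow no sign-flip p under 0.0625, and over arrays its permutation p was 0.0593, so this stays open.

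Each count was set beside those of 100 splits of the same arrays into groups of the same sizes, the real split included. In 1 of 100 splits, the real one, the count was as large for smoke against air at 2 h (1726, highest other 369) and 24 h (7276, 4801), both treatments against dexamethasone (404, 324 and 2281, 853) and against air (515, 367 and 1813, 189), the change of the smoke effect between times (5522, 303) and air between times (15858, 10612). No lower share is possible with 100 splits, and these splits do not keep the arrays of a rat apart. For the interaction and for changes of an effect between times, the mean difference by dexamethasone or by time was removed before regrouping. Within these limits chance is argued against for the comparisons where only the real split was as large. It cannot be excluded for dexamethasone against air (100 of 100 at 2 h, real 0, highest other 35; 49 at 24 h, 1, 114), both treatments against smoke (12 at 2 h, 4, 108; 9 at 24 h, 112, 1484), the interaction (100 at 2 h, 0, 135; 47 at 24 h, 1, 317) or the change of the dexamethasone effect (100, 0, 2). Nor can it for the lists by camera at its preset correlation: smoke 41 at 2 h (8, 13) and 51 at 24 h (11, 19), dexamethasone 5 at 2 h (15, 17) and 57 at 24 h (10, 17). For the pooled dexamethasone effect 1 of 100 splits at 2 h (12, 2) and 3 at 24 h (29, 328) gave as large a count. These shares do not exclude chance, because the pooled effect was chosen after the single comparisons were seen. At 24 h 51 of the other splits called at least 1 probeset. Splits with several times the real count (114, 108, 1484, 135, 317, 328) point to a structure of the samples. One known structure is that Xist was high and Eif2s3y low on all arrays of rat 4 at 2 h. The same held for rats 5 and 6 and dexamethasone array 2 at 24 h, so the 2 times differ in this respect. Whether it accounts for those splits was not tested. With the rat as a block and labels swapped within rats, which keeps the arrays of a rat apart as the random splits do not, the real split was the highest of 32 for smoke at 2 h (2488, 789), for both treatments against dexamethasone (716, 425 and 3447, 1596), against air (1012, 517 and 2908, 2855) and against smoke at 2 h (8, 7), and of 16 for smoke at 24 h (8597, 5655), where 16 splits are too few for a share under 0.05. Both treatments against smoke at 24 h gave 141, with 2 of 16 splits as large and a highest other of 218, and dexamethasone against air gave 0 at 2 h (32 of 32) and 3 at 24 h (8 of 32, highest other 82). At 24 h this block counts dexamethasone array 2 with a number it does not match.

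Of 180 checks of a gene or measure in a group for a lone extreme array, 17 found 1. Chance alone gives about 1 in 20 where values are continuous and independent, which does not hold here. Muc5ac is flagged whenever a single array lies above a floor that the others share. The flags of Col1a1 and Krt5 at 2 h each repeat the same rat. The excess over 1 in 20 is therefore not evidence of odd arrays. In log2 intensity, air array 2 at 24 h stood apart in Hmox1 (11.97) and Muc5ac (5.54), air array 6 at 24 h in Ccn2 (12.88) and air array 5 at 24 h in Mmp12 (6.99). Muc5ac was above the floor on a single array in 3 other groups: air 4 at 2 h (5.26), both treatments 3 at 24 h (4.75) and smoke 5 at 2 h (5.99). Col1a1 was low in rat 4 at 2 h in all 4 conditions: air 12.08, both treatments 12.12, dexamethasone 12.22 and smoke 11.81. Rat 4 was also the only rat at 2 h with high Xist and low Eif2s3y. Krt5 was low in rat 6 at 2 h in air (11.14) and with both treatments (11.03). Array 5 of both treatments at 24 h was low in Hmox1 (12.42) and Scgb1a1 (12.57). Dexamethasone array 6 at 24 h was low in Gclm (9.59) and dexamethasone array 3 at 24 h high in Cxcl1 (12.79).

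By the test of the difference itself, the smoke effect differed between 24 h and 2 h in 5522 probesets. The named ones were Tac1 (3.76), Fosl1 (3.61), Xirp1 (3.47), Csf3 (3.39), Lgals4 (3.29), Il6 (1.58), Cxcl1 (0.84), Hmox1 (0.79; without smoke array 2 at 2 h 0.65, adjusted p = 0.0825) and Gclm (0.74) upward and E2f8 (-3.69), Top2a (-3.59), Cdca3 (-3.42), Hsd17b6 (-3.38) and Pclaf (-3.16) downward. For Cyp1a1 the fit gives 1.97. That is the 24 h effect alone, since all 6 air and all 6 smoke arrays at 2 h lay at the floor. The interaction with dexamethasone at 24 h passed in 1 probeset, that of Rbm11. Its fitted value of -0.59 is not a measured size, since at 24 h 5 of 6 air and all 6 dexamethasone arrays lay at the floor, and the call ended with dexamethasone array 2 as a rat of its own (adjusted p = 0.0504). Among the control probesets, which no comparison uses, those of beta-actin were higher with dexamethasone than in air at 2 h, by 0.15 at the 3' end, 0.24 at the 5' end and 0.19 in the middle.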

How the results depend on the processing

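The alternatives with a floor of 32, with dexamethasone array 2 at 24 h as a rat of its own, or without the arrays numbered 2 at 24 h were chosen after the data were seen. Of 618 calls of named genes, 610 held under quantile normalization, 607 under median centring, 618 with trend and robust, 595 with array weights, 433 with only the groups compared, 585 with probesets averaged per gene, 588 with the description number, 584 with the RNA quality covariate, 585 with a floor of 32 and 451 with any single array left out; the dim filter kept 518 of the 518 it tested. The rat block kept 376 of 383, random block 234 of 235, own-rat block 371 of 383, and 413 of 505 held without the arrays numbered 2; the lost calls had the same direction, and 1 call reversed: Nr3c1 with both treatments against air at 24 h was -0.21 and 0.11 (adjusted p = 0.824) with probesets averaged per gene. The cause was not tested unless stated.

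Counts that moved by over 1.5 times are, for dexamethasone against air at 24 h (D24), both treatments against dexamethasone (DSD), smoke (DSS) and air (DSA), and the interaction (I), as follows. Rat block: D24 3, DSD 716 at 2 h and 3447 at 24 h, DSS 8 at 2 h, DSA 1012 at 2 h and 2908 at 24 h; it moved no other count by as much and, among named genes, ended the calls of Tgm1, C1qc, C1qb, Fcer1g, Gdpd2, Lgi1 and, for DSA at 2 h, Il6, and no other. Calls that arose were Ccn2 for smoke at 2 h, Fkbp5, Col1a1 and Foxj1 for smoke at 24 h, and Fkbp5 and Col1a1 for DSD at 24 h. Own-rat block, with D24 at 1 and DSD at 2711 at 24 h moved by less: DSD 699 and DSS 8 at 2 h, DSA 1029 at 2 h and 2935 at 24 h, I 0 at 24 h (lowest adjusted p 0.0504). Array weights: dexamethasone against air 2 at 2 h and 9 at 24 h, DSD 4140 at 24 h, DSS 12 at 2 h and 379 at 24 h, DSA 973 at 2 h and 3668 at 24 h, I 19 at 24 h. Only the groups compared, fewer arrays per fit: smoke at 24 h 4704, D24 0, DSD 13 at 2 h and 1234 at 24 h, DSS 0 at both times, DSA 131 at 2 h, I 1 at 2 h and 0 at 24 h. Without the arrays numbered 2 at 24 h: DSD 1226, DSS 55, DSA 681, I 0, with fewer arrays. Probesets averaged per gene, with fewer features tested: smoke 838 at 2 h and 4012 at 24 h, D24 3, DSD 221 at 2 h and 1347 at 24 h, DSS 1 at 2 h and 55 at 24 h, DSA 252 at 2 h and 1069 at 24 h, change of the smoke effect 3100, air between times 8313. Dim filter: D24 0, DSS 66 at 24 h, I 0 at 24 h. Floor of 32: D24 3, I 6. Description number: D24 0, I 3. Quantile normalization: I 4, and median centring: I 2, both at 24 h. With an estimated correlation the lists that shifted numbered 0 for smoke at 2 h, 1 at 24 h and 0 for dexamethasone at both times. The correlation of smoke effects without and with dexamethasone was 0.908 at 2 h and 0.871 at 24 h over probesets called in at least 1 of them. The balance of rises and falls turned at 24 h for smoke with the dim filter (3158 higher, 3232 lower), for DSD with median centring (1343, 1038) and only the groups compared (688, 546). It also turned for DSS with the dim filter (42, 24) and trend and robust (58, 55). For DSA it turned with the dim filter (909, 917), trend and robust (896, 911), the RNA quality covariate (839, 872) and both rat blocks (1411, 1497 and 1412, 1523). Low signal limits Rbm11, Muc5ac, Btnl5 and Cyp1a2, which lie near the floor.

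With 1 array left out, counts ranged from 1159 to 1978 for smoke at 2 h, 5392 to 7943 for smoke at 24 h, 0 to 1 and 0 to 9 for dexamethasone, 142 to 666 and 1526 to 2870 for DSD, 2 to 14 and 7 to 1110 for DSS, 239 to 596 and 1111 to 2191 for DSA, 0 to 0 and 1 to 157 for I, 4435 to 6281 for the change of the smoke effect, 0 to 1 for that of dexamethasone, and 15251 to 15520 for air between times.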

Other observations

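The zinc-finger class, its shared-sequence test and the test of mixed RNA were chosen only after the result was seen; the test of expression level was laid down before its value was seen.

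Other gene groups differed between air at 24 h and air at 2 h, in different rats. Of 15 circadian clock genes 9 were lower and 3 higher (the same adjusted over the list alone; adjusted p = 0.402 with an estimated correlation), with Cry2 (-2.00 ± 0.13) and Dbp (-1.63 ± 0.14) down. Of 26 NRF2 targets 15 were higher and 2 lower (the same alone; adjusted p = 0.422 with an estimated correlation), Slc7a11 by 2.10 ± 0.24. Of 18 chaperones of the endoplasmic reticulum 11 were higher and 2 lower (13 and 2 alone; adjusted p = 0.518 with an estimated correlation), and of 20 secretory markers 12 were lower and 1 higher (12 and 2 alone; adjusted p = 0.402 with an estimated correlation), Cyp2f4 by -3.12 ± 0.22.

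Zinc-finger genes, those with a symbol that starts with Zfp or Znf and a digit, were frequent among the rises with smoke at 2 h. Of 229 such genes 63 rose and 7 fell, that is 27.5% higher against 2.18% of other genes (odds ratio 17.0, Fisher's exact p = 2.27e-47; p = 0.00062 for the class by camera with an estimated correlation; genes are not independent). With dexamethasone present 33 of 229 rose (14.4% against 0.443%). At 24 h 41 rose and 14 fell with smoke (17.9% higher against 13% of other genes). Here the tests differed, with Fisher's exact p = 0.0372 but p = 0.377 by camera with an estimated correlation. Of 10000 gene lists matched on mean level, 121 held as many rises. With dexamethasone present 8 rose at 24 h (3.49% against 3.78%, Fisher's exact p = 1). In air 131 were higher and 34 lower at 24 h than at 2 h (57.2% higher against 31.3%). Fisher's exact p was 1.31e-15, and p = 0.0655 by camera with an estimated correlation. The hypothesis that the expression level of the class accounts for the 63 is argued against: 0 of 10000 gene lists matched on mean level held as many rises (highest 20). Whether probesets that share sequence account for it stays open, since the number of 63 genes was known when the limit of its test was set.

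Air array 4 at 24 h held Xist at 8.53% to 14.6% of the level of high arrays on its 4 probesets, against lower levels on the other arrays of that rat (839 and a mean of 54.6 in intensity on the brightest). Other arrays with high Eif2s3y held raised Xist as well, though less. On that probeset array 6 of both treatments at 2 h had 413 and dexamethasone array 3 at 2 h had 260. Smoke array 4 at 24 h, of the same rat, had 111, while dexamethasone array 2 at 2 h had 8.99. Those arrays were not tested for mixed RNA. RNA of another animal mixed into this array is a candidate explanation that the tables leave open. On the 205 animal markers the slope towards a 10% mix, where 1 is such a mix, was 0.715 ± 0.142 (SE) for rat 5, 0.644 ± 0.106 for dexamethasone array 2 and 0.558 ± 0.124 for rat 6, the sources high in Xist. It was 0.139 to 0.429 for rats 1 to 3, so no single source stands out. The array is in each 24 h comparison with air. Without it the count was 6644 for smoke, 4 for dexamethasone and 1564 for both treatments against air.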
